A study of Mus musculus with 43 samples.

How the data were processed

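RNA was measured with Affymetrix Mouse Gene 1.0 ST arrays on 43 samples of immune cells sorted from male C57BL/6 mice aged 6 weeks. Per the labels, cells came from untreated mice or from mice taken 2 h after a subcutaneous injection of 10000 U of interferon alpha, an antiviral cytokine of the type I interferon family. The labels name TriZol extraction and amplification with the Ambion WT Expression Kit. The cells were labelled as spleen cells, except macrophages from the peritoneal cavity. The source of CD8+ T cell baseline arrays 1 and 2 reads blood against a spleen title, and the preparation of macrophage baseline arrays 1 and 2 names spleen, so the tissue of these 4 arrays is in doubt and the titles were followed. No vehicle injection is labelled for the baseline mice. Nothing in the labels says whether the arrays came from separate animals, so the p-values measure only the spread between these arrays.

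The deposited values are an intensity for each probe set and array on a linear scale, and the submitters' processing notes name Affymetrix Power Tools and RMA, a method that summarises probes and normalises across arrays. Their versions and the genome build are not given in the sources used here. The values ran from 4.69 to 22042, array medians lay between 105 and 125, and they were log2-transformed here without further scaling. No detection calls were used, and the number of arrays limits the precision. Of 24922 probe sets, 21425 carried 1 gene symbol, 1399 carried several and 2098 carried none. Where a symbol had more than 1 probe set, as 921 did, the brightest was used, which left 19752 genes. Symbols are those of the platform annotation, which can be old.

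Samples fell into 18 groups, which were 9 cell types at baseline or after interferon. All groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 25 residual degrees of freedom), so that the single interferon array of macrophages was assumed to vary like the other groups. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 within the comparison and its change was at least 1 on the log2 scale. The comparisons were the interferon effect in each cell type, its unweighted mean over the 9 cell types, the effect in 1 cell type minus the mean effect in the other 8, and an F test for any difference of the effect among cell types. All p-values printed beside single genes are these adjusted limma p-values, two-sided.

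Genes named in the text were taken by a fixed rule. It allowed the 25 largest rises and 15 largest falls on average, the 15 largest rises and 10 largest falls in each cell type, and the 6 largest positive and 4 largest negative differences from the other 8. Each had to be called, to keep its sign at adjusted p below 0.05 with a preparation term, and in a cell type to separate every interferon array from every baseline array. Predicted models, loci and small RNAs were counted and not named. Members of the fixed gene lists could be named as well, and those named were picked after their values were seen. There were 42 lists, for interferon-stimulated functions, immune and metabolic pathways, stress responses and cell type markers, and 486 of their 557 genes were measured. The remaining list genes are not reported here. Lists were tested with camera against all other genes at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists within a comparison. The groups, tests, gene lists, naming rule and most alternative settings were chosen before the data were examined.

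Preparation is described differently among the labels. Baseline replicates 1 and 2 share a wording. Baseline replicate 3 shares another with the interferon arrays of CD8+ T cells, regulatory T cells, gamma-delta T cells, dendritic cells and neutrophils. The interferon arrays of CD4+ T cells, NK cells and NKT cells carry a wording that no baseline array carries, and macrophage baseline replicate 3 and the macrophage interferon array give none. Wording and treatment were thus wholly confounded in CD4+ T cells, NK cells, NKT cells and neutrophils and partly in the others. A term for the wording of baseline replicates 1 and 2 against all others was therefore added in a separate fit (24 residual degrees of freedom), and another fit compared the interferon arrays with baseline replicate 3 alone (17 residual degrees of freedom). Neutrophils had no replicate 3, and for CD4+ T cells, NK cells and NKT cells replicate 3 does not match the wording of the interferon arrays. The other alternatives were each cell type fitted alone, replicate number as a fixed or random block, dim genes left out (log2 level of at least 7 in at least 2 arrays, 12349 genes), quantile normalisation, a variance trend with robust moderation, array weights, the mean of probe sets, each array left out in turn, and, both chosen after seeing the data, 3 arrays with a large spread around their group left out and neutrophils left out. The raised and lowered counts of a cell type, its named genes and its named differences were tried only without arrays of that same type. Baseline levels were correlated with changes by exact permutation tests in scipy 1.17.1, with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

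The model was tested on simulated data. Their noise was normal, independent and, for each gene, of equal spread on all arrays, as the model assumes. Unequal spread among the real arrays was therefore not tested. In every cell type and on average, a change of 3 on the log2 scale was recovered in 100 percent of the changed genes. A change of 1.5 was recovered in 91 to 100 percent, with at most 6 false calls among 19752 genes, and data simulated without a change gave 0 calls. The F test recovered 73 percent of genes changed by 1.5 in neutrophils only and 98 percent of those changed by 3, with 8 false calls.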

Results

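The arrays covered 6 lymphocyte types, namely CD4+ T cells, CD8+ T cells, regulatory T cells, gamma-delta T cells, NK cells and NKT cells, and 3 further types, dendritic cells, macrophages and neutrophils. Each type had 3 baseline arrays except neutrophils, which had 2, and 2 interferon arrays except macrophages, which had 1. The 26 baseline and 17 interferon arrays had median intensities between 105 and 125, and all 43 arrays were most similar to other arrays of their own cell type. Correlations to the rest of the group were at least 0.958, with no value for the single macrophage interferon array. The design text of the series speaks of 11 populations, of which 9 were analysed here.

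The first question was which genes responded to interferon across immune cells. Rsad2, which encodes the antiviral protein viperin, rose 20.9 times on average over the 9 cell types (log2 change 4.38, SE 0.0911, 17 interferon against 26 baseline arrays). Ifit3b and Ifit3, members of a family of RNA-binding antiviral proteins, rose by 4.85 (SE 0.113) and 4.32 (SE 0.0908), and Cxcl10, a chemokine that attracts activated T cells, rose by 4.66 (SE 0.105). Mx1 and Mx2, genes of the dynamin-like GTPase family, rose by 4.17 (SE 0.108) and 4.30 (SE 0.0949). Usp18, a protease that removes ISG15 and restrains interferon signalling, rose by 3.75 (SE 0.0893). Scd2, which encodes a fatty acid desaturase, fell by 1.55 (SE 0.0902), and the amino acid transporter gene Slc43a2 fell by 1.26 (SE 0.0864). In all, 248 genes were raised and 13 lowered on average, with adjusted p = 5.66e-28 for Rsad2 and 7.65e-16 for Scd2. Preparation as a term gave 221 raised and 13 lowered genes, of which 212 and 10 were the same calls, and baseline replicate 3 alone gave 221 and 7, of which 210 and 6 were the same. The 25 named rises, chosen among other things for an adjusted p below 0.05 with the preparation term, were called against baseline replicate 3 alone, while the smaller falls of Ubald1, Rflnb and Herpud1 came to -0.94, -0.98 and -0.93 with the preparation term, short of a 2-fold change.

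**Figure D1:**
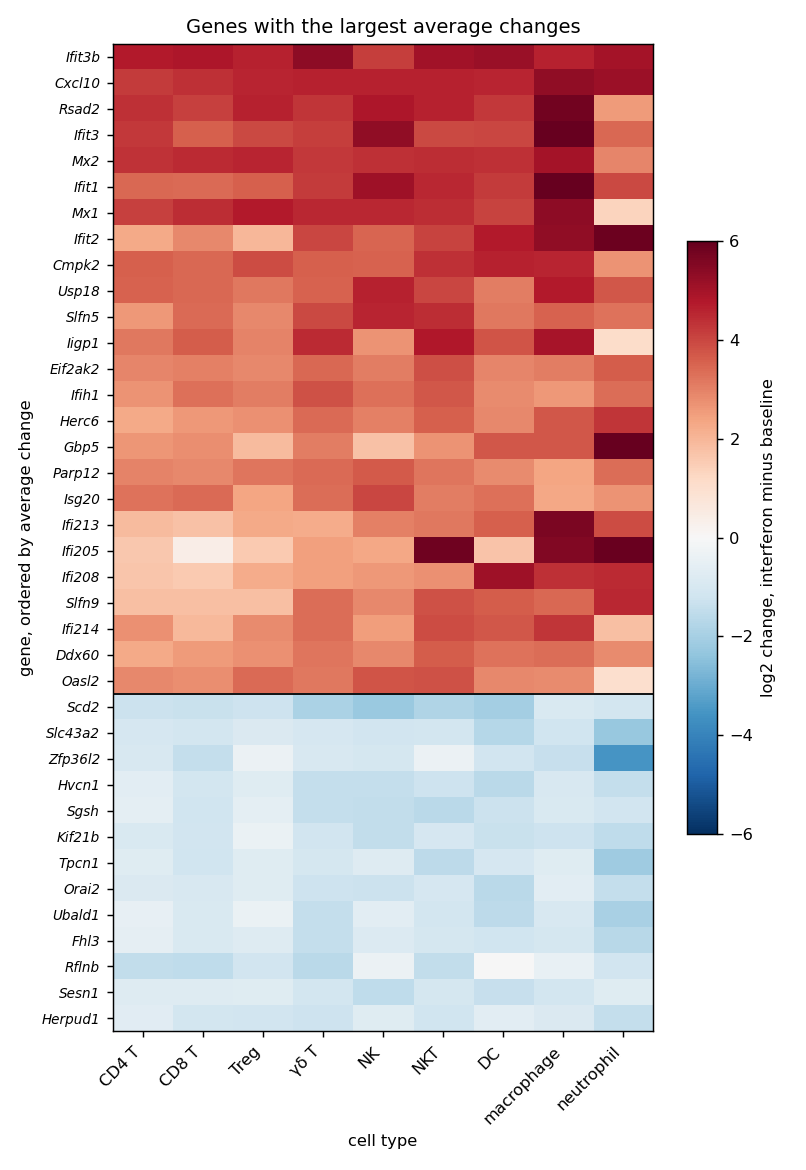
The log2 change after interferon of the genes with the largest average rises (25) and falls (13), in rows, is drawn by colour for each of the 9 cell types in columns. The rises run through nearly every column, whereas Scd2, the largest fall, was called lower in 8 of the 9 cell types.

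The gene lists fixed for interferon functions rose in every cell type. Of 22 measured antiviral effectors, 17 to 20 were raised in each type and none was lowered, with the same 17 to 20 when adjusted over the list alone. Of 13 genes of the ISG15 and ubiquitin-like pathway, 10 to 13 were raised, and all 7 interferon-inducible GTPases, which act against intracellular pathogens, were raised in all 9 types. Of 16 nucleic acid sensors, 10 to 14 were raised, among them Ifih1, which detects double-stranded RNA, at 3.18 on average (SE 0.0985). Of 7 schlafen genes, which regulate lymphocyte growth and restrict viruses, 5 to 7 were raised, with Slfn5 at 3.54 on average (SE 0.113). Of 17 genes of MHC class I presentation, 2 to 9 were raised, and H2-T24 was raised in all 9 types. With an estimated correlation, these 6 lists held their camera call in every cell type, with adjusted p for antiviral effectors between 1.96e-09 in regulatory T cells and 0.00036 in neutrophils, and for MHC class I between 0.00362 in regulatory T cells and 0.0195 in macrophages. Over all lists and the 9 cell types, 172 camera calls were made at the preset correlation and 93 held with an estimated one.

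Among signalling genes, Irf7, the transcription factor that amplifies interferon production, rose by 2.55 on average (SE 0.0833), and Stat2, a part of the interferon-activated transcription complex, rose by 2.46 (SE 0.0829). Cd69, an early activation marker that retains lymphocytes in tissue, was raised in all 9 types and by 2.42 on average (SE 0.0861). Cd274, which encodes the inhibitory ligand PD-L1, was called raised in 8 of the 9 types, with an average of 2.34 (SE 0.101), and its change in dendritic cells was 1.00 (SE 0.29, adjusted p = 0.0289), just short of a 2-fold rise, and 0.69 (adjusted p = 0.116) with the preparation term. Tnfsf10, the gene of the death ligand TRAIL, rose by 2.79 on average (SE 0.0949), and the cell death genes Xaf1, Daxx and Mlkl rose by 2.31 (SE 0.0543), 2.35 (SE 0.0664) and 2.43 (SE 0.0929). The cell death list, with 4 to 6 of 18 genes raised per type, held its call with an estimated correlation except in CD4+ T cells (adjusted p = 0.0715) and gamma-delta T cells (adjusted p = 0.0523). The 18 trafficking receptors moved lower together in CD8+ T cells, regulatory T cells, gamma-delta T cells and NK cells and on average (median -0.36 on average, adjusted p = 0.0101 with an estimated correlation), while in CD4+ T cells and macrophages the call was lost (adjusted p = 0.0932 and 0.161 with an estimated correlation).

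**Figure D2:**
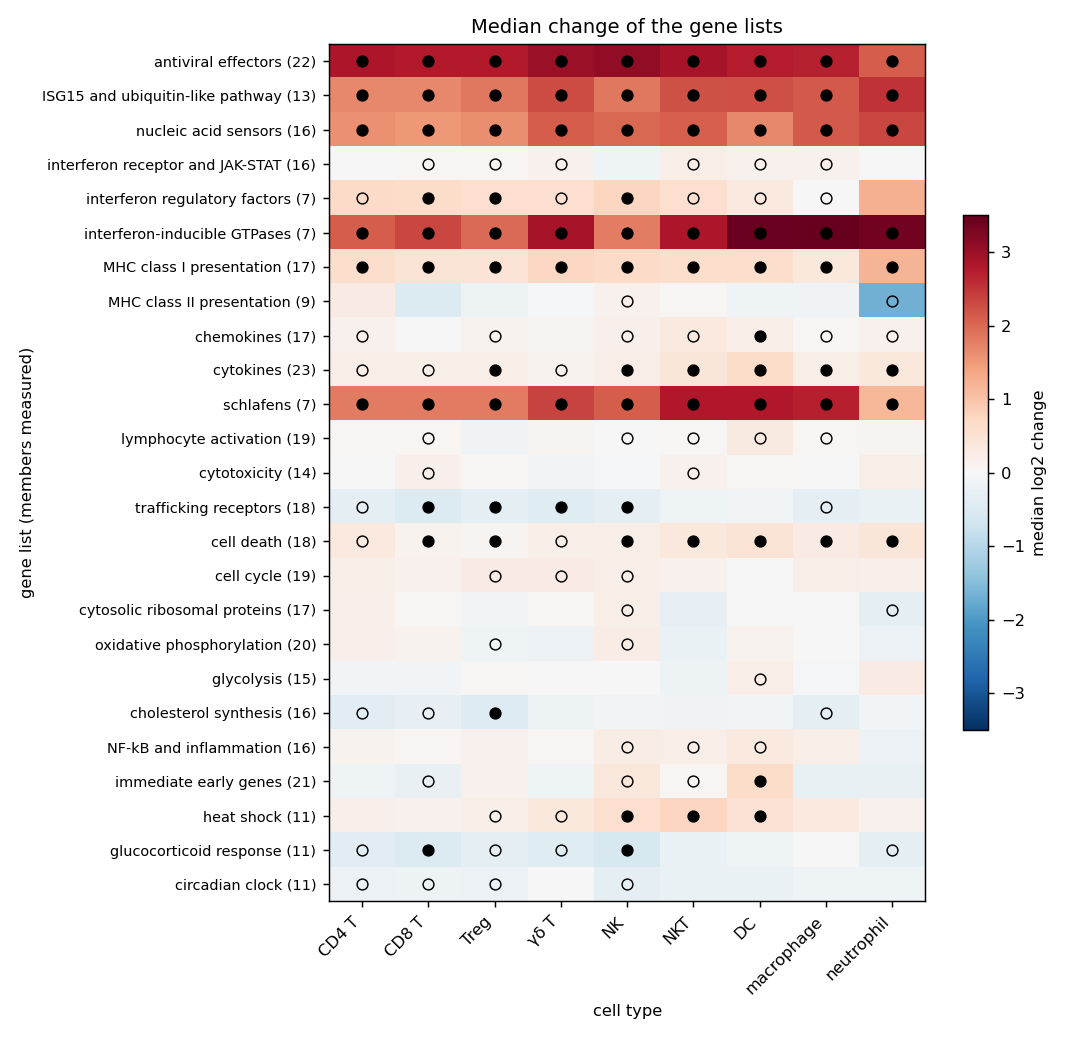
The median log2 change of each gene list except the marker lists (rows) is drawn by colour in each cell type (columns). An open circle marks an adjusted p below 0.05 with camera at the preset correlation. A filled circle marks a call that also held with an estimated correlation. The 6 interferon and MHC class I lists carry filled circles in all 9 cell types.

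The number of responding genes in each cell type came next. Raised genes numbered 178 in CD4+ T cells, 198 in CD8+ T cells, 220 in regulatory T cells, 302 in gamma-delta T cells, 246 in NK cells, 571 in NKT cells, 463 in dendritic cells, 266 in macrophages and 480 in neutrophils. Lowered genes numbered 13, 63, 5, 135, 106, 75, 160, 52 and 563 in the same order. With the preparation term the raised genes numbered 160, 173, 198, 269, 219, 556, 423, 246 and 425, and the lowered genes 15, 54, 4, 132, 118, 72, 179, 52 and 664. Against baseline replicate 3 alone, where neutrophils gave no value, the raised genes numbered 184, 145, 162, 270, 176, 252, 370 and 179 and the lowered genes 4, 13, 10, 336, 168, 109, 54 and 80. The raised genes of the lymphocyte types other than NKT cells varied less between fits than the lowered ones. Leaving out 1 array changed the raised genes of NKT cells to 875, without baseline replicate 3. In the same way the lowered genes of CD4+ T cells came to 6, 5, 109 and 8 without baseline replicates 1, 2 and 3 and interferon replicate 1, and those of regulatory T cells to 3, 3 and 1 without baseline replicates 1 and 2 and interferon replicate 2. Those of CD8+ T cells came to 41 without interferon replicate 1, those of dendritic cells to 80 without interferon replicate 2, and those of macrophages to 96 without baseline replicate 1. Those of gamma-delta T cells came to 240, 361 and 34 without baseline replicate 1 and interferon replicates 1 and 2, and those of NK cells to 65, 241, 68 and 63 without baseline replicates 1, 2 and 3 and interferon replicate 2. Those of neutrophils came to 269 and 1024 without interferon replicates 1 and 2.

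**Figure D3:**
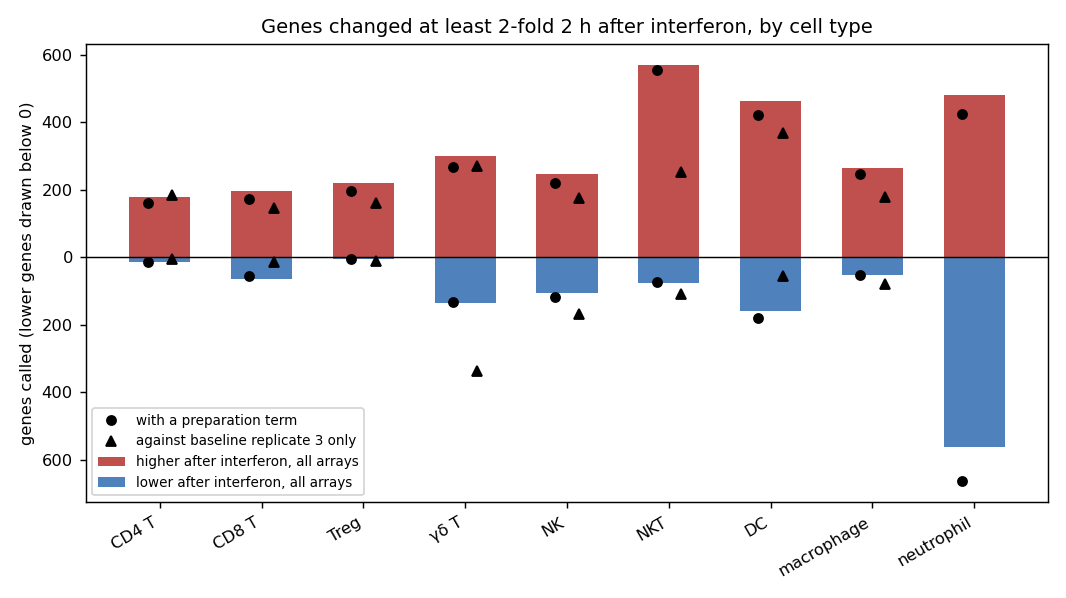
Bars give the number of genes raised and lowered at least 2-fold after interferon in each cell type, circles the number with a preparation term and triangles the number against baseline replicate 3 alone, which neutrophils lack. With all types fitted together neutrophils had the most lowered genes, 563, and NKT cells the most raised, 571, whereas each type fitted alone gave NKT cells 259 raised genes and dendritic cells 485.

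In CD4+ T cells, CD8+ T cells and regulatory T cells the largest rises were mostly genes raised in all 9 types. Ifitm3, which blocks virus entry and was raised in the 6 lymphocyte types only, went in CD4+ T cells from a log2 level of 6.62 ± 0.17 (SD, n = 3) to 10.97 ± 0.90 (n = 2), a rise of 4.35 (SE 0.462, adjusted p = 4.2e-08). Mx1 rose by 4.75 (SE 0.31, adjusted p = 4.9e-13) in regulatory T cells and by 4.42 (SE 0.31, adjusted p = 2.49e-12) in CD8+ T cells. Gzmb, the gene of the cytotoxic protease granzyme B, rose by 2.47 (SE 0.449) in CD8+ T cells, by 2.65 (SE 0.449) in gamma-delta T cells and by 2.80 (SE 0.449) in NKT cells. Ifng, which encodes interferon gamma, rose in CD4+ and CD8+ T cells, gamma-delta T cells, NK cells and NKT cells, from 1.08 (SE 0.223) in CD4+ T cells to 1.68 (SE 0.223) in gamma-delta T cells, although against baseline replicate 3 the CD4+ change was 1.11 with adjusted p = 0.0619. Vipr1, the receptor gene for vasoactive intestinal peptide, fell in CD4+ T cells by 1.45 (SE 0.201) and in CD8+ T cells by 1.49 (SE 0.201), but with the mean of its probe sets the changes were -0.98 and -0.91. Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell by 1.13 (SE 0.154) in regulatory T cells. The 16 genes of cholesterol synthesis moved lower together in regulatory T cells (median -0.46, adjusted p = 0.0188 with an estimated correlation), with 0 members called over all genes and 1 when adjusted over the list alone, and against baseline replicate 3 the adjusted p was 0.064 with an estimated correlation.

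In gamma-delta T cells Iigp1, an interferon-inducible GTPase, rose by 4.50 (SE 0.246, adjusted p = 1.65e-14), from 6.08 ± 0.51 (SD, n = 3) to 10.57 ± 0.12 (n = 2). Scd2 fell by 1.92 (SE 0.259). Klrb1c and Klrb1a, which encode NK cell receptors, fell by 1.93 (SE 0.276) and 1.75 (SE 0.348), and the Klrb1a change was -0.92 (adjusted p = 0.29) against baseline replicate 3 alone. The median level of the NK cell markers was 8.80 on baseline array 1, 7.51 and 6.09 on baseline arrays 2 and 3, and 6.89 and 6.97 on the interferon arrays. B cell markers also varied among the gamma-delta T cell arrays, between 7.21 and 9.96.

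In NK cells Sh2d1b2, the gene of the adaptor EAT-2B that acts behind activating receptors, rose from 5.36 ± 0.77 (SD, n = 3) to 10.41 ± 0.06 (n = 2), a change of 5.05 (SE 0.326, adjusted p = 2.36e-13), against a mean change of 0.49 in the other 8 types. That difference of 4.56 (SE 0.347, adjusted p = 2.34e-10) was 3.65 against baseline replicate 3 alone (adjusted p = 0.000333). In NKT cells Sh2d1b2 also changed more than in the other 8 types, by 1.65. In NK cells Ifit3 rose by 5.30 (SE 0.261). S1pr1, the receptor that guides lymphocytes out of lymphoid organs, fell by 2.11 (SE 0.257, adjusted p = 4.57e-07), and the chemokine receptor gene Cxcr4 fell by 1.69 (SE 0.228). The glucocorticoid response list had 4 of 11 genes lowered, Cxcr4, Il7r, Sgk1 and Zfp36l2, and moved lower as a set (adjusted p = 0.0138 with an estimated correlation), with the same 4 genes adjusted over the list alone. Zfp36l2 in NK cells came to -0.96 (adjusted p = 0.104) with the preparation term, and Il7r to -1.14 (adjusted p = 0.115) against baseline replicate 3 alone. The cytokine gene Csf2 rose by 1.59 (SE 0.217) and Myc, a transcription factor of cell growth, by 1.79 (SE 0.256).

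In NKT cells Ifi205, of a family of intracellular DNA-binding proteins, rose by 5.84 (SE 0.414, adjusted p = 1.77e-12), from 5.05 ± 0.65 (SD, n = 3) to 10.89 ± 1.29 (n = 2). Its level was 1.82 higher on interferon array 1 than on array 2, and it reached 12.36 on the macrophage interferon array. Macrophage RNA in the NKT sort therefore stays open for this rise. Mmp13, which encodes a collagenase, changed by 2.87 more in NKT cells than in the other 8 types (SE 0.294, adjusted p = 2.86e-07), and Mmp9, which encodes a gelatinase, fell by 2.63 (SE 0.264) and differed from the others by -2.16 (SE 0.281, adjusted p = 5.07e-05). Both differences were called against baseline replicate 3 alone, at 2.78 and -2.29. The macrophage gene Mertk and the sensor gene Tlr8 were raised more than in the other types, by 1.98 (SE 0.32) and 1.96 (SE 0.342), but without interferon replicate 1 these differences were 1.38 (adjusted p = 0.227) and 1.18 (adjusted p = 0.412). The median level of the macrophage markers was 9.26 and 8.25 on the interferon arrays and between 7.07 and 8.31 on the baseline arrays of NKT cells.

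In dendritic cells Tnfsf10 rose by 4.74 (SE 0.273, adjusted p = 1.33e-14), from 5.56 ± 0.19 (SD, n = 3) to 10.30 ± 0.35 (n = 2), and by 2.18 more than in the other 8 types (SE 0.291, adjusted p = 6.46e-06). Kdr, the gene of a receptor for vascular endothelial growth factor, differed from the other types by 3.22 (SE 0.207, adjusted p = 2.03e-12), and Hspa1a, which encodes an inducible heat shock protein, by 2.49 (SE 0.311, adjusted p = 2.19e-06). The immediate early genes, first responders to many stimuli, had 6 of 21 members raised, and 6 adjusted over the list alone, and rose as a set (median 0.63, adjusted p = 0.0216 with an estimated correlation). As a difference from the other 8 types this set held as well (median 0.73, adjusted p = 0.023 with an estimated correlation), while against baseline replicate 3 alone the adjusted p within dendritic cells was 0.0635 with an estimated correlation. Nr4a3 and Atf3, transcription factors of that list, rose by 2.47 (SE 0.242) and 2.42 (SE 0.324). Cd40, a costimulatory receptor, rose by 2.16 (SE 0.272), and the inflammatory cytokine gene Il6 by 1.99 (SE 0.25). Mmp12, which encodes macrophage elastase, fell by 2.02 (SE 0.2). Heat shock genes had 2 of 11 members raised, 2 adjusted over the list alone. The set held with an estimated correlation in dendritic cells (adjusted p = 0.0275), NKT cells (0.0173) and NK cells (0.0205). The median level of the list separated the arrays in dendritic cells, with at most 8.670 at baseline and at least 9.661 after interferon. In NK cells baseline array 3 lay at 9.006, between the interferon arrays at 8.999 and 9.076. In NKT cells baseline array 2 lay at 8.968, above interferon array 1 at 8.868. Baseline arrays 2 of NK cells (8.044) and 1 of NKT cells (7.820) lay lowest. The list median thus did not separate treatments in NK and NKT cells.

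In macrophages, with 1 interferon array, Ifit3 had the largest rise of all genes, 6.24 (SE 0.33, adjusted p = 5.72e-15), from 5.61 ± 0.33 (SD, n = 3) to 11.86. Ccl2 and Ccl7, chemokines that attract monocytes, rose by 3.32 (SE 0.323) and 2.84 (SE 0.233), which was 3.03 (SE 0.335, adjusted p = 1.3e-06) and 2.69 (SE 0.242, adjusted p = 2.21e-08) more than in the other 8 types. Fkbp5, a target of the glucocorticoid receptor, rose by 2.48 (SE 0.33), and Socs2, a feedback inhibitor of cytokine signalling, differed from the other types by 2.84 (SE 0.458, adjusted p = 0.000556). Il6 rose by 2.37 (SE 0.316). Htr2a, a serotonin receptor gene, fell by 2.08 (SE 0.283). Against baseline replicate 3 alone, Ccl2, Fkbp5 and Htr2a changed by 3.54, 2.20 and -1.82 and stayed called.

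In neutrophils Gbp5, a guanylate-binding protein of inflammasome defence, rose by 6.13 (SE 0.291, adjusted p = 1.23e-16), from 6.58 ± 0.22 (SD, n = 2) to 12.71 ± 0.003 (n = 2). Lipg, which encodes endothelial lipase, and Acod1, the gene of the enzyme that makes itaconate, rose by 4.24 (SE 0.202) and 4.02 (SE 0.24), or 3.70 (SE 0.213, adjusted p = 7.55e-14) and 3.54 (SE 0.253, adjusted p = 1.22e-11) more than in the other 8 types. Fcgr1, a high-affinity antibody receptor, rose by 4.06 (SE 0.339), and Il18, a cytokine processed by inflammasomes, by 3.45 (SE 0.409). MHC class I presentation had 9 of 17 genes raised, and 9 adjusted over the list alone, and Nlrc5, its transcriptional activator, rose by 3.16 (SE 0.32). Ifnar1, which encodes a chain of the interferon alpha receptor, fell by 1.34 (SE 0.225, adjusted p = 6.24e-05), a difference of -1.25 from the other types (SE 0.238, adjusted p = 0.000937). Zfp36l2, an RNA-decay protein gene, fell by 3.56 (SE 0.336). Of 9 MHC class II genes, 6 were lowered, and 7 adjusted over the list alone, with H2-Aa at -4.29 (SE 0.812), but the call of the list was lost with an estimated correlation (adjusted p = 0.433). The B cell markers had a median level of 8.80 and 7.93 on the baseline arrays of neutrophils and 6.05 and 6.23 on the interferon arrays, and 7 of 10 were lowered, among them Cd79a by -3.37 (SE 0.567). Preparation could not be compared within neutrophils, since both baseline arrays carried 1 wording and both interferon arrays another.

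**Figure D4:**
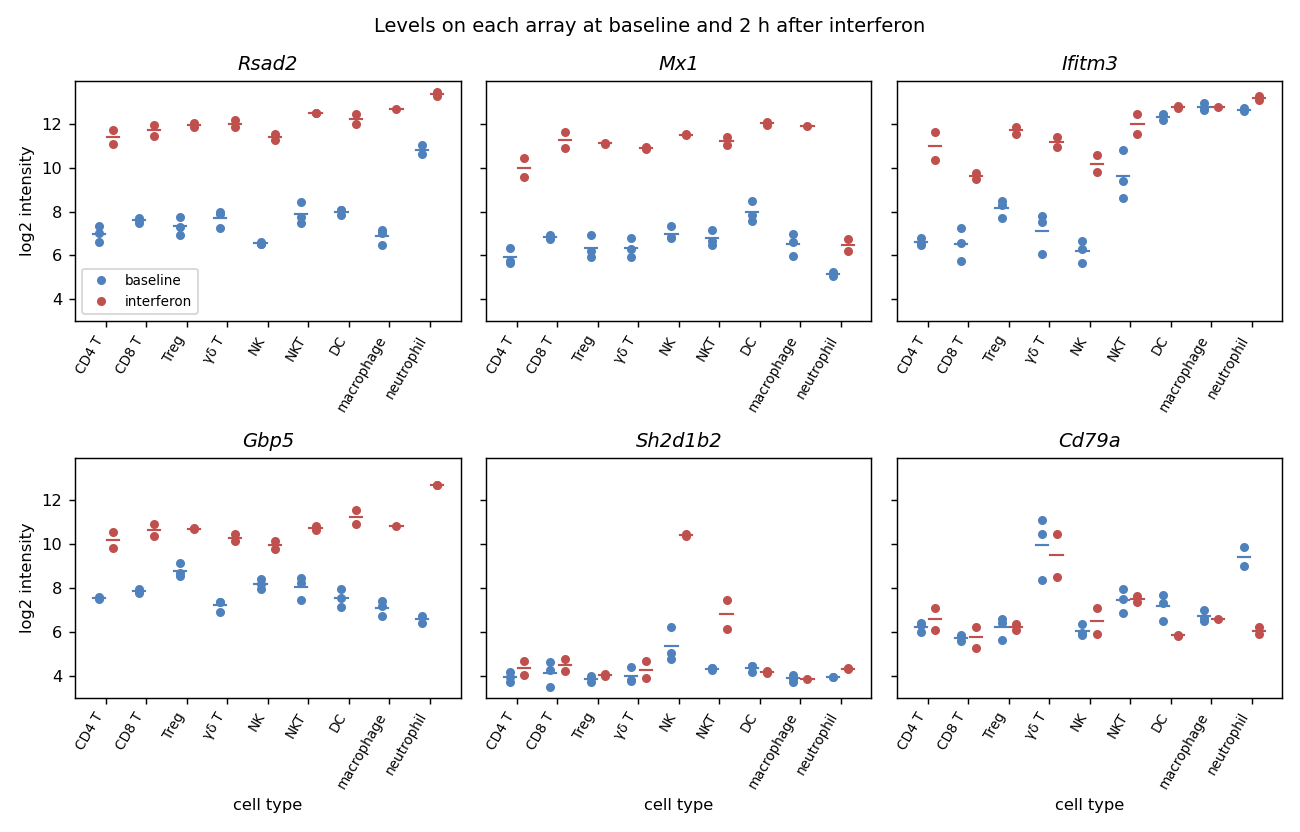
Log2 levels of Rsad2, Mx1, Ifitm3, Gbp5, Sh2d1b2 and Cd79a are plotted for every array (points) with group means (bars), at baseline and after interferon in the 9 cell types. Rsad2 rose in all types, Mx1 reached a mean of 6.48 in neutrophils, Sh2d1b2 reached 10.41 in NK cells, and Cd79a was lower on the interferon arrays of neutrophils.

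Whether the response itself differed among cell types was tested directly. The F test called 822 genes over the 9 types and 433 over the 8 types without neutrophils, against 118 over these 8 with baseline replicate 3 alone. Of 100 assignments of the arrays to treatment within cell types, the real one included, 3 gave as many F test genes, up to 2426. Genes whose change differed from that of the other 8 types, up and down, numbered 206 and 258 in neutrophils, 177 and 60 in dendritic cells, 58 and 8 in NKT cells, 51 and 20 in macrophages, 16 and 26 in NK cells, 3 and 6 in regulatory T cells, 1 and 4 in gamma-delta T cells, 0 and 5 in CD4+ T cells and 0 and 8 in CD8+ T cells. These sum to 907. Of the same 100 assignments, 11 gave a sum as large, up to 1625. Reassignment spreads the shared interferon response unevenly over the types, so these assignments do not stand for equal responses. Chance was therefore not excluded by them for the F test or for the sum. With the preparation term the differences numbered 198 and 284 in neutrophils and 182 and 64 in dendritic cells. That term is 1 shift shared by all cell types and largely cancels from a difference between types, so these counts say little about preparation. Against baseline replicate 3 alone, dendritic cells had 127 and 15 and macrophages 25 and 20, NKT cells had 4 and 10, and CD4+, CD8+ and regulatory T cells had 0. Without 1 array, the counts up and down ranged from 128 to 256 and 110 to 479 in neutrophils, 104 to 193 and 28 to 81 in dendritic cells, 14 to 383 and 3 to 14 in NKT cells, 39 to 83 and 18 to 33 in macrophages and 2 to 22 and 0 to 60 in NK cells. In regulatory, gamma-delta, CD4+ and CD8+ T cells they ranged from 0 to 6 up and 0 to 15 down. The 58 of NKT cells came to 41, 29 and 383 without NKT baseline replicates 1, 2 and 3, and to 301 without 3 arrays with a large spread, a fit chosen after seeing the data. With array weights, which did not converge, they came to 366, and the 51 of macrophages to 196. The order of the cell types by these counts was therefore not settled. For single genes, only arrays of the cell type itself were left out in turn, so any single array below means 1 of those. The 6 largest positive differences of dendritic cells were called under that fit and without any single array, and those 6 of neutrophils without any single array. The 6 of macrophages were called under that fit, which compares 1 array with 1, and without any single baseline array, while their only interferon array could not be left out.

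Shared and restricted responses were then counted. In total, 1065 genes were raised in at least 1 cell type, 208 in at least 5 and 90 in all 9, among them Rsad2, Cxcl10, Irf7, Cd69, Tnfsf10 and Socs1, a feedback inhibitor of cytokine signalling. Exactly 1 type raised 554 genes, and for 236 of these the change also differed from that in the other 8 types, 102 of them in neutrophils, 84 in dendritic cells, 23 in NKT cells and 19 in macrophages. Lowered genes numbered 912 in at least 1 type and 12 in at least 5, and 451 of the 748 lowered in exactly 1 type were lowered in neutrophils. Across the 1955 genes called in any type, which are not independent replicates, the log2 changes of CD4+ and CD8+ T cells correlated most closely (r = 0.908), and those of NK cells and neutrophils least (r = 0.598). The median r was 0.825 over the 15 pairs of lymphocyte types, 0.689 over the 18 pairs of a lymphocyte type with another type, and 0.724 over all 36 pairs. Over all genes, not only those called, r was lower, at 0.702 for CD4+ and CD8+ T cells, and lowest for NKT cells and neutrophils (0.357), while NK cells and neutrophils had 0.485. The medians over the same pairs were then 0.613, 0.528 and 0.552, and CD4+ T cells correlated less with NKT cells (0.372) than with neutrophils (0.527). With the preparation term the median over all pairs of the called genes was 0.706.

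The resting level of interferon genes was compared with the size of the response. The median log2 level of 42 antiviral effector, ISG15 pathway and GTPase genes at baseline ran from 7.96 in macrophages to 8.73 in neutrophils, and their median change from 2.05 in regulatory T cells to 2.68 in NKT cells. Over the 9 cell types no relation of level and change was detected (Pearson r = -0.298, exact permutation p = 0.432; Spearman rho = -0.1, exact permutation p = 0.81, both two-sided). Without macrophages and NK cells, the types farthest from the median level, r was -0.235. With the preparation term r was -0.356 (exact permutation p = 0.344), and with means in place of medians r was -0.541 (exact permutation p = 0.134) and rho -0.45 (exact permutation p = 0.23). Level and change share the baseline arrays, and with the level from replicates 1 and 2 and the change against replicate 3, r was 0.0977 over 8 types (exact permutation p = 0.821).

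Finally, baseline replicate 3 was compared with baseline replicates 1 and 2 over the 8 types that had all 3. Ccna2, the gene of cyclin A2, was higher in replicate 3 by 1.21 (SE 0.153, adjusted p = 0.000732), and the mitotic genes Ccnb2 and Top2a by 0.91 (SE 0.136) and 0.80 (SE 0.138), each in 8 of 8 cell types. The interferon-inducible gene Slfn1 was higher by 0.64 (SE 0.089, adjusted p = 0.000907), also in 8 of 8. Mki67, a further cell cycle gene, was higher in 6 of 8, with -0.57 in CD4+ T cells and -0.11 in dendritic cells. At 2-fold or more, 3 genes were called higher and 0 lower in this limma contrast, and 160 higher and 56 lower at any fold, while 1776 and 1189 had an unadjusted p below 0.05. The 19 cell cycle genes were higher as a set (median 0.42, adjusted p = 0.0411 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone.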

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

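The tests of B cells and of dendritic cells in the neutrophil sort, both tests of a ceiling in neutrophils, the split of the NKT genes by macrophage level and the comparison of NKT baseline array 1 with the other NKT baseline arrays, in calls and in size, were chosen only after the result was seen. Every gene below came up because its response in 1 cell type differed from the mean response of the other 8 cell types, and the difference itself was tested with limma. Up to 3 positive and 2 negative differences were taken per cell type, and the values are differences of log2 changes. Arrays were left out in turn only within the cell type named, so any single array below means 1 of that type. Arrays of the other 8 types were not left out for these genes.

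In T cells, Ifit2, an RNA-binding antiviral gene, responded less in CD4+ T cells (-1.78, adjusted p = 0.00526) and in regulatory T cells (-2.07, adjusted p = 0.000573), although it rose in both. Ccnj, a cyclin gene, differed by -1.497 in CD4+ T cells. In CD8+ T cells the DNA-binding protein gene Ifi205 differed by -2.96 and the antibody receptor gene Fcgr1 by -1.78. In regulatory T cells St3gal6, a sialyltransferase gene, Atg13, an autophagy gene, and Gng12, a G protein gene, differed by 1.35, 1.33 and 1.24, and the guanylate-binding protein gene Gbp5 by -1.41. In gamma-delta T cells Jaml, an adhesion molecule gene, differed by 1.06, and the NK receptor genes Klrb1c and Klrc2 by -1.55 and -1.502. None of these was called against baseline replicate 3 alone, where Ifit2 came to -1.26 (adjusted p = 0.29) in CD4+ T cells and -1.96 (adjusted p = 0.184) in regulatory T cells.

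Only Ifit2 in regulatory T cells stayed called without any single array. In CD4+ T cells, without interferon replicate 1, Ifit2 came to -1.52 (adjusted p = 0.247) and Ccnj to -1.18 (adjusted p = 0.176). In CD8+ T cells, without that replicate, Ifi205 came to -3.001 (adjusted p = 0.114) and Fcgr1 to -1.77 (adjusted p = 0.326). In regulatory T cells, without interferon replicate 2, St3gal6 came to 1.16 (adjusted p = 1), Atg13 to 1.23 (adjusted p = 1), Gng12 to 1.01 (adjusted p = 0.851) and Gbp5 to -1.42 (adjusted p = 0.815). In gamma-delta T cells, Jaml came to 0.90 (adjusted p = 0.152) without interferon replicate 1, and without interferon replicate 2 Klrb1c came to -1.63 (adjusted p = 0.214) and Klrc2 to -1.27 (adjusted p = 0.335).

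In NK cells Sh2d1b2 differed by 4.56 and stayed called without any single NK cell array. The stress gene Gadd45g differed by 1.74, and Sh2d1b1, the neighbour of Sh2d1b2 in the same adaptor family, by 1.72. Gbp5 differed by -1.55 and Nt5e, which encodes the ecto-enzyme CD73, by -1.502. Without interferon replicate 2, Gadd45g came to 1.74 (adjusted p = 0.19), Sh2d1b1 to 1.76 (adjusted p = 0.0761), Gbp5 to -1.37 (adjusted p = 0.245) and Nt5e to -1.33 (adjusted p = 0.267). Against baseline replicate 3 alone only Sh2d1b2 of these was called, with Gadd45g at 1.29 (adjusted p = 0.492), Sh2d1b1 at 1.47 (adjusted p = 0.229), Gbp5 at -1.15 (adjusted p = 0.391) and Nt5e at -1.73 (adjusted p = 0.0848).

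In dendritic cells the growth factor receptor gene Kdr differed by 3.22, Prrg4, a membrane protein gene, by 2.58, the heat shock gene Hspa1a by 2.49 and the elastase gene Mmp12 by -2.11, and all 4 stayed called without any single array and against baseline replicate 3 alone. The entry inhibitor gene Ifitm3 differed by -2.30 in dendritic cells and by -2.77 in macrophages, where it did not rise. Its difference came to -2.33 (adjusted p = 0.0745) without dendritic cell interferon replicate 2 and to -2.68 (adjusted p = 0.0647) without macrophage baseline replicate 2, and against baseline replicate 3 alone to -2.56 (adjusted p = 0.0789) and -3.18 (adjusted p = 0.0796). In macrophages the interferon-inducible genes BC023105 and Ifi213 differed by 3.62 and 2.91, the chemokine gene Ccl2 by 3.03 and Jaml by -2.20, each also called against baseline replicate 3 alone, 1 array against 1.

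In neutrophils the lipase gene Lipg, the itaconate enzyme gene Acod1 and Gbp5 differed by 3.70, 3.54 and 3.34, and Ms4a4c, a membrane protein gene that rose in the other types, by -3.91. H2-Aa, an MHC class II gene, differed by -4.05, and by -3.60 (adjusted p = 0.0748) without baseline replicate 1. The median change of the 10 B cell markers in neutrophils was -1.85, and 9 of them lay at a log2 level of 7 or more at baseline, so the lower class II genes are consistent with B cells in the baseline sort. The lowered class II genes would need dendritic cells like those sorted here at 4.27 percent or more, and the 5 of 10 dendritic cell markers that this share would raise at least 2-fold, Flt3 and Cd209a among them, lay a median of -1.27 (IQR 0.322) from the level it gives, which argues against dendritic cells as the whole source. Clec9a, 1 of the 5, lay at -0.176, and all 10 markers had a median of -0.677 with Itgax at 1.03, so a smaller part from dendritic cells stays open. The preparation wording and the treatment cannot be told apart for these genes, since both changed together in neutrophils and only 2 of the other 8 types had B cell markers at a level of 7 or more, so their median difference of 0.216 between baseline replicate 3 and replicates 1 and 2 decides nothing. A loss of class II expression by the neutrophils themselves was not tested.

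In NKT cells Ifi205 differed by 3.15, the collagenase gene Mmp13 by 2.87, the chemokine gene Cxcl9 by 2.76, the gelatinase gene Mmp9 by -2.16 and the repressor gene Hic1 by -1.42. Mmp13 and Mmp9 stayed called without any single array, while without interferon replicate 1 Ifi205 came to 2.24 (adjusted p = 0.0541), Cxcl9 to 2.19 (adjusted p = 0.333) and Hic1 to -1.20 (adjusted p = 0.257). Against baseline replicate 3 alone Cxcl9 came to 1.51 (adjusted p = 1), and the other 4 were called.

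The 58 genes called higher in NKT cells than in the other 8 types were a median of 0.283 higher on the interferon array with more macrophage signal, between the bounds of 0.25 and 0.5 written before the test. For the 22 genes at least 2-fold lower in the peritoneal macrophages than in NKT cells, such as Dpp4, this median was -0.107. As a set these 22 genes did not follow the macrophage signal between the 2 interferon arrays. However, 7 of them, such as Mmp13 (1.51) and Cxcl9 (1.14), were higher on the array with more of that signal. The 22 genes were picked for a low level on 1 array of peritoneal macrophages, which favoured a low median, and the NKT cells came from spleen. Macrophage RNA therefore stays open for them. For the other 36 genes, such as Ifi205 (1.82), Mertk and Tlr8, the median was 0.693, as macrophage RNA in the NKT sort would give. Without NKT baseline array 1, 50 percent of the 58 genes stayed called, which met the result written beforehand for a deviant array, but 44.8 percent stayed called without array 2 and 100 percent without array 3, so a deviant array stays open for the calls. Their median difference was 1.38 (IQR 0.479) with all arrays and 1.27 (IQR 0.53), 1.29 and 1.56 without baseline arrays 1, 2 and 3. All 58 stayed above 0 each time, which argues against 1 deviant baseline array as the whole source of the size. The 58 genes were chosen on these same arrays, however, so part of the remaining size was given in advance. Without interferon arrays 1 and 2 the median was 1.22 and 1.56. Of the 29 calls lost without baseline array 1, 12 ended by p alone, 3 by fold alone and 14 by both. A shift shared by baseline arrays 1 and 2 stays open, since the median was 0.988 against replicate 3 alone. A response of NKT cells themselves was not tested and stays open as well.

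Of 42 interferon genes, 8 responded less in neutrophils than in the other 8 types and 5 responded more. The 8 genes, among them Rsad2, Oas2 and Oasl2, had a median interferon level 1.09 above the mean of the other types, which is consistent with a ceiling. For Mx1, Mx2 and Iigp1 the median lay at -3.85, but they were chosen by that same level after it was seen, so this median decides nothing. Their baseline levels were 5.152, 5.205 and 5.119 in neutrophils, against means of 6.711, 5.561 and 6.246 in the other types. These genes rose in neutrophils, so their baseline had to lie below the low interferon level they were chosen by. The baseline levels are therefore not a separate test, and a ceiling was not decided for these genes. Over all 42 genes the median difference was 0.15, which argues against a general compression of changes on the neutrophil arrays. A difference of regulation between cell types was not tested and stays open.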

How the results depend on the processing

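Leaving out 3 arrays with a large spread and leaving out neutrophils were chosen after seeing the data. The 25 largest average rises and the 15 largest rises of each cell type, from Rsad2 to Gbp5, were chosen partly for keeping their sign and an adjusted p below 0.05 with the preparation term, so that fit says little about them. They stayed called with quantile normalisation, without any single array and, except in neutrophils, where it gives no value, against baseline replicate 3 alone. For the rises of a cell type, only arrays of that type were left out in turn. The only interferon array of macrophages could not be left out for macrophage genes. Falls held less well. Against replicate 3 alone, 6 of 13 on average, 1 of 10 in CD4+ T cells and 10 of 10 in NK cells stayed called.

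Each cell type fitted alone gave 11 lowered genes in regulatory T cells, 188 raised and 22 lowered in gamma-delta T cells, 259 raised in NKT cells and 16 lowered in macrophages. Against baseline replicate 3 alone, lowered genes numbered 4 in CD4+ T cells, 13 in CD8+ T cells, 10 in regulatory T cells, 336 in gamma-delta T cells, 168 in NK cells, 54 in dendritic cells, 80 in macrophages and 7 on average, raised genes in NKT cells 252, F test genes 118, summed differences 215 and genes raised in exactly 1 type 352, in a fit with fewer arrays and no neutrophils. Without neutrophils, all other arrays gave 433 F test genes, summed differences of 433, 467 genes raised in exactly 1 type, 8 lowered on average and a median correlation of 0.772, and 264 of 291 named gene values stayed called, the others being mostly differences of T cell types. Quantile normalisation gave 3 lowered genes in regulatory T cells, 80 in macrophages and 1449 F test genes. Array weights, which did not converge, gave 142 lowered genes in CD4+ T cells, 8 in regulatory T cells, 263 in NK cells, 172 in macrophages and 22 on average, 417 raised in macrophages, 8527 F test genes and summed differences of 1868. Without the 3 arrays, lowered genes numbered 147 in CD4+ T cells, 245 in gamma-delta T cells and 119 in macrophages, and F test genes 1682. The cause was not tested for these.

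The median correlation between cell types was 0.706 with the preparation term and 0.739 with replicate number as a block. The changes did not pair by number (median r of same-numbered arrays 0.0354, 7 of 16 above 0.1). Camera calls fell from 172 to 93 with an estimated correlation, and resting level against change reversed to r = 0.0977 on separate arrays. The cause was not tested.

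Without 1 array, lowered genes ranged from 5 to 109 in CD4+ T cells, 41 to 78 in CD8+ T cells, 1 to 4 in regulatory T cells, 34 to 361 in gamma-delta T cells, 63 to 241 in NK cells, 80 to 223 in dendritic cells, 38 to 96 in macrophages and 269 to 1024 in neutrophils. Raised genes in NKT cells ranged from 398 to 875, and the median correlation from 0.713 to 0.764, the latter over 8 types without macrophages.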

Other observations

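The array reassignments in this part were planned, and the genes were picked from the fixed lists after their values were seen. Il15, a cytokine that sustains NK cells, was raised in NK cells (2.03), NKT cells (2.70), dendritic cells (2.84), macrophages (2.65) and neutrophils (1.69, SE 0.332). In NKT cells its level was 1.3 higher on interferon array 1, with more macrophage signal, than on array 2. It was 10.47 on the macrophage interferon array and 8.84 in NKT cells after interferon. Macrophage RNA in the NKT sort stays open for that rise. Csf1, the growth factor gene of macrophages, was raised in CD4+ T cells (1.06), regulatory T cells (1.48), gamma-delta T cells (1.21), NK cells (1.42), NKT cells (1.51), dendritic cells (1.60) and macrophages (1.91, SE 0.271). Bcl2l11, which encodes the death protein BIM, was lowered in CD8+ T cells (-1.31), gamma-delta T cells (-1.04) and NK cells (-1.23, SE 0.272).

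The unnamed probe sets, 3497 with several symbols or none, held 51 raised and 2 lowered on average. Over all genes the median change was -0.104 in NKT cells and 0.0751 in neutrophils, and -0.0794 and 0.00101 after quantile normalisation.

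Of 100 assignments of the arrays to treatment within cell types, the real one included, 1 gave as many genes called on average as the real 261, and the highest other gave 6. For the F test 3 did, up to 2426 genes, and for the summed differences from the other 8 types 11 did. Fewer than 5 was the bound written beforehand, which the genes called on average and the F test met and the sum did not. For the genes called on average this argues against chance. Reassignment spreads the shared interferon response unevenly over the cell types, so it cannot decide on chance for the F test or the sum. For baseline replicate 3 against replicates 1 and 2, 3 of 100 choices of arrays gave at least the real 216 genes at any fold. The most was 1911. The bound written beforehand was for called genes, of which the real choice had 3 higher and 0 lower. Genes at any fold were counted in their place, and called genes were not compared over the choices, so chance was not decided by that bound.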
